A study of Mus musculus with 6 samples.

How the data were processed

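RNA-seq libraries of bone marrow-derived mouse osteoclasts were compared between 3 wild-type libraries and 3 whose labels were read as *Tet2* deleted on both alleles and *Tet3* on 1 allele. Per the labels' protocols, adherent bone marrow cells were taken after 2 days in M-CSF and cultured with RANKL and M-CSF, RNA was purified on columns, and stranded libraries from mRNA were read from 1 end over 75 bases. Per the submitters' processing notes, TopHat2 2.0.13, Bowtie2 2.2.3 and SAMtools 0.1.19 were used with the mouse build mm10. The counting program, its strand setting and its annotation release are not given in the sources used here, so genes that overlap on opposite strands cannot be separated with certainty. The authors deposited whole-number raw counts per Ensembl gene, not normalized, with symbols and coordinates beside them.

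The deposited table had 23264 rows, of which 60 repeated a gene with identical counts and were dropped, leaving 23204 genes. It held 0 mitochondrial chromosome rows. Of the identifiers, 99.8% matched the GENCODE M21 annotation of the same build, and 99.3% of these had the same start and end. Column names gave the genotype but no replicate number, so each column was assigned to its genotype only; the replicate numbers and sexes in the labels were not tied to columns, since column names do not give them. No fit with a replicate block, a sex term, male libraries alone or a genotype-by-sex interaction was run for that reason. The labels do not number the animals, and p-values measure the spread between these libraries. Every pair of libraries differed by more than sampling noise (chi-square per degree of freedom of 27.5 or more), so none was counted as a repeated deposit of 1 library; this does not show that they came from different animals or cultures.

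Total counts per library were 8794973, 12354672 and 12845879 for wild-type libraries 1, 4 and 6. They were 14267135, 9519978 and 13849747 for libraries 2, 3 and 5, labelled mutant. Counts were scaled by TMM and tested in edgeR 4.0.16 under R 4.3.3 with the quasi-likelihood test, after filterByExpr left 14040 genes, with genotype as the only term and Benjamini-Hochberg adjustment to a threshold of 0.05. CPM values are TMM-scaled. Standard errors were computed as the size of the log2 fold change over the square root of the F statistic. *Tet2* and *Tet3* were also tested by a two-sided exact permutation test. The design fixed before the data were examined allowed for normalized values or counts; the deposited values were counts, so the count test was used. The common biological coefficient of variation was 40.9%, and 23.5% with the naming batch as a term, which limits what 3 libraries per genotype can resolve.

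Gene lists were fixed before the data were examined and tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 where 5 or more members were tested, and again with an estimated correlation and with fry. The lists covered osteoclast genes, V-ATPase subunits, cell fusion, negative regulators, secreted factors, macrophage, dendritic cell, neutrophil, stromal, lymphocyte, and mast cell or erythroid markers, interferon and inflammatory genes, cell cycle, oxidative phosphorylation, glycolysis, cholesterol synthesis, apoptosis, stress, imprinted and germline genes, the DNA methylation machinery, and sex-linked genes given as counts. Genes were named by a rule also fixed then: *Tet2* and *Tet3*; up to 12 rises and 12 falls past the threshold whose libraries do not overlap and whose mean reaches 1 CPM in the higher group, ordered by fold, or the 5 genes with the smallest p where fewer than 5 pass in a direction; up to 4 members of each list past the threshold or otherwise the 2 with the highest mean; and always *Nfatc1*, *Acp5*, *Ctsk*, *Mmp9*, *Dcstamp* and *Tnfrsf11a*. Predicted, ribosomal and mitochondrial genes and near-identical copies were counted but skipped in naming. Other genes were named after their values were seen, except the sex-linked genes and the markers picked beforehand for the tests on pituitary hormone genes. A few list members, among them 1 picked by the rule, are not reported here by name, and the counts and tests of their lists include them.

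The test was tried on simulated counts with 200 changed genes, in a single simulation for each fit. The changed genes were drawn only from genes above a minimum mean count, and each gene was simulated independently. The rates below may therefore not hold for genes with few counts or for genes that move together. For the genotype comparison, run on 13591 simulated genes, it recovered 20% of genes changed 2-fold and 83% of those changed 4-fold, and 12 of its 115 calls (10.4%) were unchanged genes, above the 5% aimed at (the threshold of 0.05). With the naming batch as a term, on 13755 genes, it recovered 63% and 95%, and 9 of 167 calls (5.39%) were unchanged genes. Counts for that fit were simulated with a difference along the naming batch, and those for the genotype comparison without any. The gain in recovery therefore does not show that a batch term is right for the real libraries. Alternatives were no filter, a stricter filter of 5 CPM in 3 libraries, DESeq2 size factors, robust empirical Bayes, limma-voom with library quality weights, an adjusted p under 0.1, a log2 fold change of 1 or more, DESeq2 1.42.0, and leaving out each library in turn. The naming batch as a term, libraries 1 to 4 alone, leaving out libraries 2 and 4, and a filter on libraries 5 and 6 were added after the data were seen. Pseudogene sequences were aligned to mitochondrial transcripts of GENCODE M21 with blastn 2.17.0. Figures were drawn with matplotlib 3.10.9.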

Results

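RNA was sequenced from mouse osteoclasts, the multinucleated bone-resorbing cells of the monocyte lineage. They were grown from C57BL/6 bone marrow with the growth factor M-CSF and then with RANKL, the cytokine that drives osteoclast formation. The 6 libraries were 3 wild type and 3 labelled Tet2Rank–/–; Tet3aRank+/–, read here as both copies of *Tet2* and one copy of *Tet3* deleted. The labels do not spell out what Rank or the a in Tet3a stands for. TET2 and TET3 are enzymes that oxidise methylated cytosine. The series title names the effect of TET deletion on DNA methylation in osteoclasts as its subject. DNA methylation itself was not analysed here. Libraries are called by the number that opens their column name. Libraries 1, 4 and 6 were wild type, and libraries 2, 3 and 5 were labelled mutant. The total count per library was between 8794973 and 14267135. The 3 totals of one genotype overlapped those of the other. Columns of libraries 5 and 6 carried a second number in their names, and those of libraries 1, 2, 3 and 4 did not. This split, with both genotypes on each side, is called the naming batch. It was also the largest split of the libraries. The leading principal component of log CPM held 68.1% of the variance and separated libraries 5 and 6 from libraries 2, 3 and 4, with library 1 between them. The next held 15.3% and separated the genotypes.

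*Tet2* (ENSMUSG00000040943, chromosome 3, 133463679 to 133545139, mm10) was lower in the libraries labelled mutant, at 52.0 CPM ± 6.32 (SD, n = 3) against 77.3 CPM ± 4.90 (SD, n = 3), or 67.3% of wild type. *Tet3* (ENSMUSG00000034832, chromosome 6, 83362373 to 83459084) was not lower. It stood at 153 CPM ± 11.4 (SD, n = 3) against 131 CPM ± 12.4 (SD, n = 3), or 117% of wild type. This goes against what loss of a *Tet3* copy would give if transcripts were lost with it. The raw *Tet2* counts were 615, 1045 and 989 in libraries 1, 4 and 6 and 831, 447 and 702 in libraries 2, 3 and 5. *Tet3* gave 1243, 1568 and 1579 counts in the wild-type libraries and 2332, 1382 and 2090 in those labelled mutant. The log2 fold change of *Tet2* was -0.57 (SE 0.120, edgeR quasi-likelihood adjusted p = 0.0924), and its libraries did not overlap. With the naming batch as a term the value was -0.57 with an adjusted p of 0.0400 (edgeR). *Tet3* had a log2 fold change of 0.23 (SE 0.117, edgeR adjusted p = 0.360). The two-sided exact permutation p was 0.1 for *Tet2* and 0.2 for *Tet3*, and 0.1 is the smallest p that 3 libraries against 3 can give. *Tet1* had between 8 and 72 counts per library. Counts were summed over whole genes, so exons outside a deleted part still count. The labels give neither the deleted parts nor whether Rank limits the deletion to some cells or stages, and either could keep transcripts; the genotype is therefore written as labelled throughout.

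The comparison of the genotypes asks which transcripts differ in osteoclasts between wild-type libraries and those labelled mutant. *Steap4*, which encodes a metalloreductase, fell from 177 CPM ± 28.9 (SD, n = 3) to 14.1 CPM ± 2.77 (SD, n = 3), the largest change among the genes that passed. The deubiquitinase gene *Stambpl1* fell from 72.3 ± 4.29 to 28.8 ± 2.22 CPM, and *Malt1*, a paracaspase of NF-kB signalling, fell from 82.1 ± 5.49 to 39.3 ± 2.31 CPM (SD, n = 3 each). The chemokine gene *Ccl6* rose from 52.3 ± 11.6 to 296 ± 41.5 CPM, the cyclic nucleotide phosphodiesterase gene *Pde3b* from 6.04 ± 1.01 to 30.6 ± 5.72 CPM, and *Trf*, which encodes transferrin, from 27.7 ± 3.13 to 100.1 ± 11.5 CPM (SD, n = 3 each). *Clec4n*, which encodes the macrophage receptor dectin-2, rose from 54.0 ± 4.002 to 187 ± 30.2 CPM, and *Cfp*, which encodes the complement factor properdin, from 129 ± 9.20 to 332 ± 25.3 CPM.

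Of 14040 genes tested, 7 rose and 3 fell at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). The log2 fold changes of the genes that rose were 2.50 for *Ccl6* (SE 0.211, chromosome 11, 83587882 to 83593087), 2.34 for *Pde3b* (SE 0.212, chromosome 7, 114415281 to 114539251), 1.86 for *Trf* (SE 0.135, chromosome 9, 103204001 to 103230444) and 1.79 for *Clec4n* (SE 0.151, chromosome 6, 123229843 to 123247021). *Nat8l*, which encodes the enzyme that makes N-acetylaspartate, had 1.58 (SE 0.154), *Cfp* 1.37 (SE 0.117), and *Xylt2*, a xylosyltransferase gene of proteoglycan synthesis, 1.25 (SE 0.119). Those of the genes that fell were -3.65 for *Steap4* (SE 0.202, chromosome 5, 7960457 to 7982213), -1.33 for *Stambpl1* (SE 0.104, chromosome 19, 34192229 to 34240333) and -1.06 for *Malt1* (SE 0.0991, chromosome 18, 65430938 to 65479067). Adjusted p-values of these 10 genes (edgeR) lay between 0.0127 for *Steap4* and 0.0438 for *Nat8l*. The next lower genes, *St18* with -1.19 and *Scd2*, a stearoyl-CoA desaturase gene, with -1.07, stayed above the threshold (adjusted p = 0.0544 for both, edgeR). In all, 2747 genes (19.6%) had an unadjusted p under 0.05, and 3769 genes (26.8%) had libraries that did not overlap between the genotypes, where chance gives 10%. The count of calls depended on how the spread was modelled. With the naming batch as a term, chosen after seeing the data, 433 genes rose and 786 fell. The 10 genes above were among them. Leaving out a library left at most 3 calls in edgeR, which was without library 2. There was 1 without library 6 and 0 without library 1, 3, 4 or 5, where 2527, 2001, 2676 and 2345 genes had an unadjusted p under 0.05. The log2 fold changes then ranged from -3.80 to -3.49 for *Steap4*, 2.32 to 2.62 for *Ccl6*, 1.75 to 1.95 for *Trf* and -1.12 to -0.99 for *Malt1*. DESeq2 on all 6 libraries called 662 genes higher and 764 lower.

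**Figure D1:**
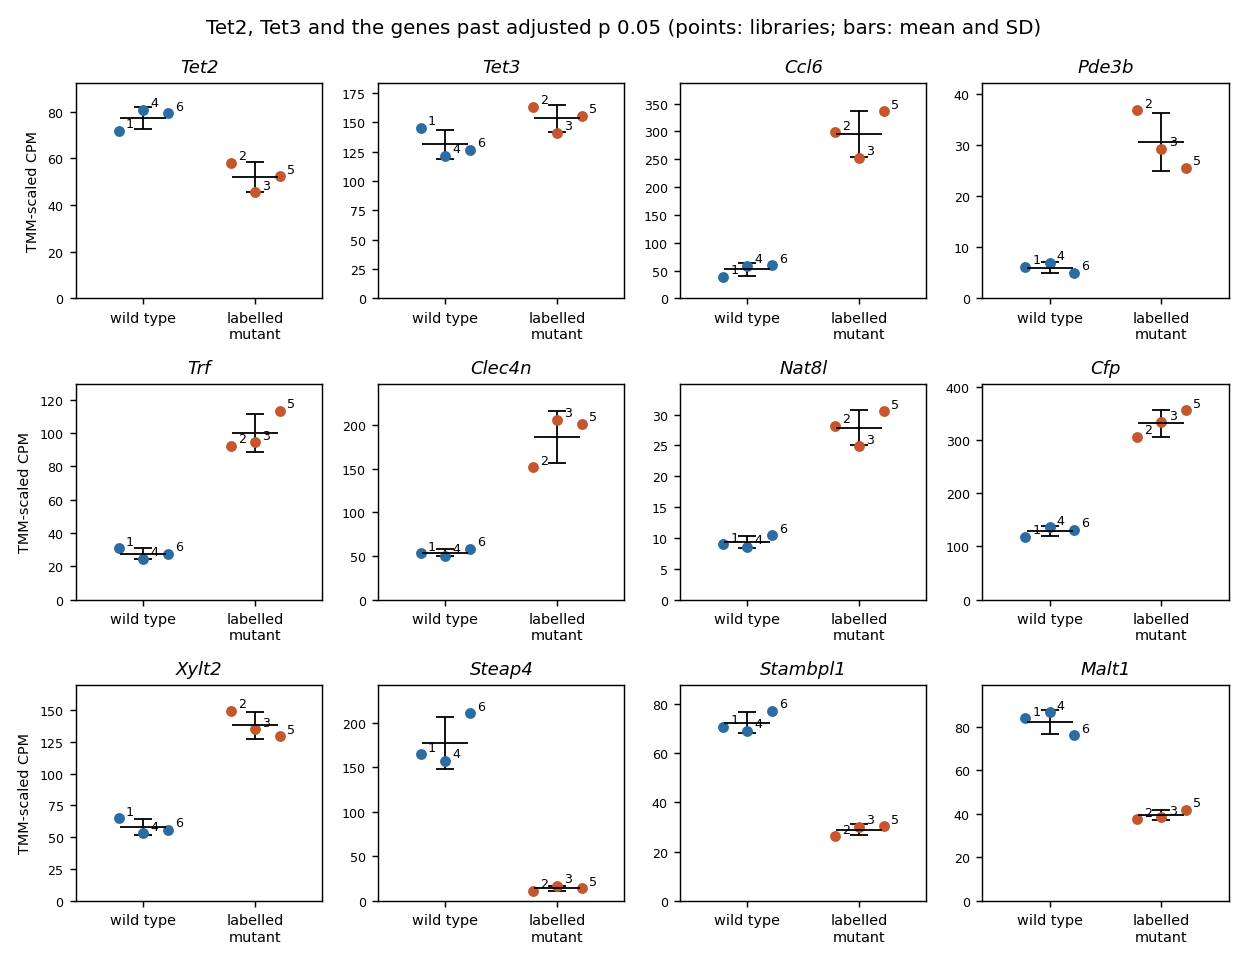
TMM-scaled CPM (vertical axes, from 0) of *Tet2*, *Tet3* and the 10 genes past adjusted p 0.05 in wild-type libraries and libraries labelled mutant, with library numbers beside the points and bars for the mean and SD of 3 libraries. *Steap4* stood at 177 CPM in wild type and 14.1 CPM in the libraries labelled mutant, and *Tet3* was not lower in the latter.

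Of the 31 genes of osteoclast differentiation and resorption tested, 29 had a log2 fold change below 0 in the libraries labelled mutant, with a median of -1.25 (quartiles -1.56 and -0.75). *Nfatc1*, the transcription factor gene that directs osteoclast formation, stood at 281 CPM ± 119 (SD, n = 3) against 920.3 CPM ± 309.7 (SD, n = 3). *Ctsk*, which encodes the collagen-degrading protease cathepsin K, stood at 2056 ± 1220.3 against 7497 ± 4032 CPM, and *Acp5*, which encodes tartrate-resistant acid phosphatase, at 1773 ± 1028 against 5421 ± 2939 CPM (SD, n = 3 each). The metalloprotease gene *Mmp9* stood at 2970 ± 1918 against 8240 ± 5126 CPM, the fusion gene *Dcstamp* at 104 ± 63.1 against 215 ± 105 CPM, and *Tnfrsf11a*, which encodes the RANKL receptor, at 67.0 ± 34.2 against 139.9 ± 55.4 CPM. Library 2 held the lowest value of each of these 6 genes and library 6 the highest. Over all genes tested, 0 of the 31 passed in edgeR and 18 had an unadjusted p under 0.05; adjusted over the list alone, 10 fell and 1 rose. The 10 that fell were *Nfatc1*, *Ctsk*, *Traf6*, *Snx10*, *Oscar*, *Ostm1*, *Jdp2*, *Atp6v0d2*, *Fosl2* and *Src*, and the 1 that rose was *Trem2*, at 403 ± 73.8 against 194 ± 61.4 CPM (named after their values were seen). With the naming batch as a term, 18 fell and 1 rose over all genes. The log2 fold changes were -1.71 for *Nfatc1* (SE 0.406, edgeR adjusted p = 0.104 and 0.0250 with the batch term), -1.87 for *Ctsk* (SE 0.578, 0.156 and 0.0243), -1.61 for *Acp5* (SE 0.575, 0.194 and 0.0378) and -1.06 for *Tnfrsf11a* (SE 0.435, 0.249 and 0.0256). *Mmp9* (-1.47, SE 0.679) and *Dcstamp* (-1.05, SE 0.585) had adjusted p-values of 0.109 and 0.164 in edgeR even with the batch term. Leaving out each library in turn, the log2 fold change ranged from -1.94 to -1.36 for *Nfatc1*, -2.39 to -1.31 for *Ctsk*, -2.10 to -1.05 for *Acp5*, -1.53 to -0.67 for *Tnfrsf11a*, -1.96 to -0.81 for *Mmp9* and -1.49 to -0.54 for *Dcstamp*. The median log2 ratio of the list was -1.19 within libraries 1 to 4 and -1.32 between libraries 5 and 6. The camera test of the list against other genes gave an adjusted p of 9.05e-12, and adjusted p = 0.443 with an estimated correlation.

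**Figure D2:**
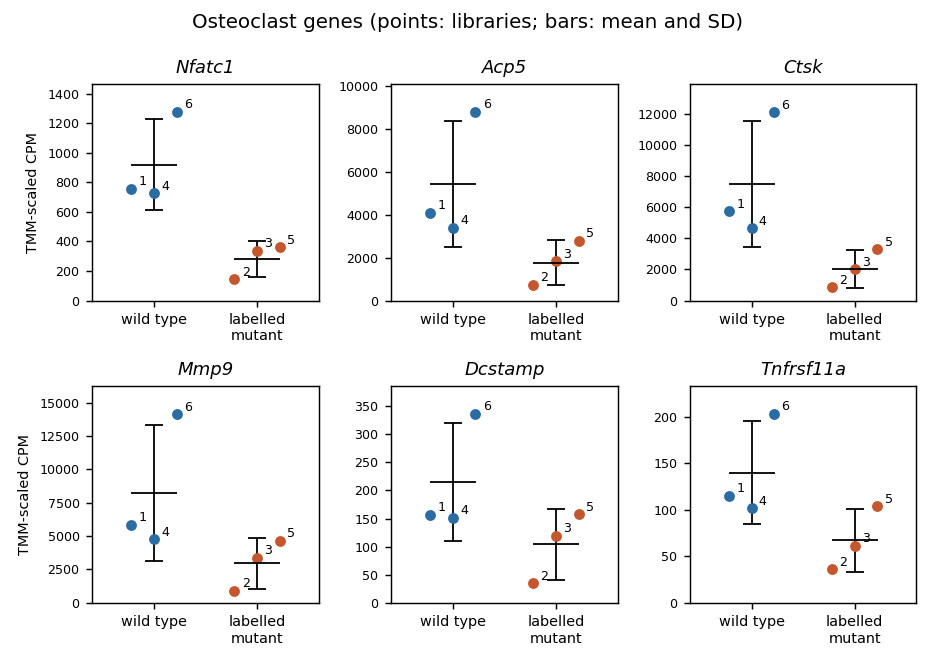
TMM-scaled CPM (vertical axes, from 0) of *Nfatc1*, *Acp5*, *Ctsk*, *Mmp9*, *Dcstamp* and *Tnfrsf11a* in wild-type libraries and libraries labelled mutant, with library numbers beside the points and bars for the mean and SD of 3 libraries. Each mean was lower in the libraries labelled mutant, such as 281 against 920.3 CPM for *Nfatc1*, and for *Dcstamp* and *Tnfrsf11a* the libraries of the genotypes overlapped.

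Most members of the V-ATPase, oxidative phosphorylation, glycolysis and cholesterol synthesis lists had a log2 fold change below 0, and 0 passed over all genes. Of 18 subunits of the V-ATPase, the proton pump that acidifies the resorption site, 16 had a log2 fold change below 0 (median -0.72). Adjusted over the list alone 12 fell and 1 rose, while 0 passed over all genes. *Atp6v1b2* stood at 1078 ± 327 against 2236 ± 663 CPM and *Tcirg1* at 1025 ± 209.8 against 1549 ± 446 CPM (SD, n = 3 each). The subunit that rose, named after its value was seen, was *Atp6v0a1*, at 195 ± 11.2 against 104 ± 19.1 CPM. All 27 nuclear genes of oxidative phosphorylation and its regulators had a log2 fold change below 0 (median -0.79), and 26 fell when adjusted over the list alone, with 0 past the threshold over all genes. *Atp5b* stood at 1026 ± 285 against 1859 ± 493 CPM and *Atp5a1* at 802 ± 156 against 1373 ± 359.7 CPM, both subunits of ATP synthase. As log2 CPM around each gene's mean, the list median per library was highest in library 6 (0.79) and lowest in library 2 (-0.68). It was 0.28 and 0.10 in libraries 1 and 4 and -0.37 and -0.14 in libraries 3 and 5. The V-ATPase list was likewise highest in library 6 (0.78) and lowest in library 2 (-0.67). Of 18 glycolysis genes, 15 lay below 0 (median -0.43) and 0 passed over all genes or adjusted over the list alone. *Aldoa* stood at 989 ± 157 against 1446 ± 290.4 CPM, and *Pkm* at 1136 ± 202 against 1159 ± 159.9 CPM. Of 20 cholesterol synthesis genes, 19 lay below 0 (median -0.44), 0 passed over all genes and 12 fell when adjusted over the list alone. *Srebf2*, a transcriptional activator of the pathway, stood at 99.1 ± 11.998 against 144 ± 16.0 CPM. The camera adjusted p was 1.36e-06 for the V-ATPase and for cholesterol synthesis, 1.17e-14 for oxidative phosphorylation and 0.00525 for glycolysis. Each list was lost with adjusted p = 0.443 with an estimated correlation, or 0.505 for glycolysis. With the naming batch as a term, 11 V-ATPase, 19 oxidative phosphorylation, 3 glycolysis and 6 cholesterol genes fell over all genes, and 1 V-ATPase gene rose.

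Of 22 macrophage markers tested, 18 had a log2 fold change above 0 (median 0.87), 1 rose over all genes (*Clec4n*), and adjusted over the list alone 10 rose and 0 fell. Besides *Clec4n* these were the complement genes *C1qa*, *C1qb* and *C1qc*, the scavenger receptor gene *Cd36*, the Fc receptor genes *Fcgr1* and *Fcgr3*, and *Mertk*, *Mrc1* and *Ccr2* (named after their values were seen). *C1qb*, for example, stood at 1438 ± 93.2 against 573 ± 142 CPM. All 14 inflammatory cytokine and chemokine genes tested were above 0 (median 1.03), of which *Ccl6* rose over all genes and *Ccl6*, *Ccl3* and *Ccl4* rose when adjusted over the list alone (the last 2 named after their values were seen). All 30 type I interferon response genes were above 0 (median 0.76), but 0 passed over all genes or adjusted over the list alone in edgeR, and 8 had an unadjusted p under 0.05. *Parp14* stood at 296 ± 76.6 against 198 ± 50.8 CPM and *Bst2* at 185 ± 45.8 against 107 ± 40.0 CPM. Libraries of the same genotype differed: the median of the interferon list per library, as log2 CPM around each gene's mean over the libraries, was 0.91 in library 2, 0.28 in library 5 and -0.28 in library 3, against -0.0152, -0.34 and -0.64 in libraries 1, 4 and 6, so library 3 lay below library 1. Of 16 dendritic cell and MHC class II genes, 13 lay above 0 (median 1.04), 0 passed over all genes and 2 (*Cd86* and *Cd83*, named after their values were seen) rose when adjusted over the list alone. *Cd74* stood at 1725 ± 1219.6 against 766 ± 296 CPM and *H2-Aa* at 609.6 ± 548 against 225 ± 128 CPM, with 3130 and 1242 CPM in library 5. The camera adjusted p was 3.41e-12 for macrophage markers (adjusted p = 0.290 with an estimated correlation), 2.03e-07 for inflammatory genes (adjusted p = 0.290 with an estimated correlation), 1.10e-08 for interferon genes (adjusted p = 0.443 with an estimated correlation) and 0.000800 for MHC class II genes (adjusted p = 0.443 with an estimated correlation). Without library 5 the MHC class II list had a camera adjusted p of 0.0562, and without library 4 it was 0.0511. With the naming batch as a term, 9 macrophage, 3 inflammatory, 6 MHC class II and 0 interferon genes rose over all genes.

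**Figure D3:**
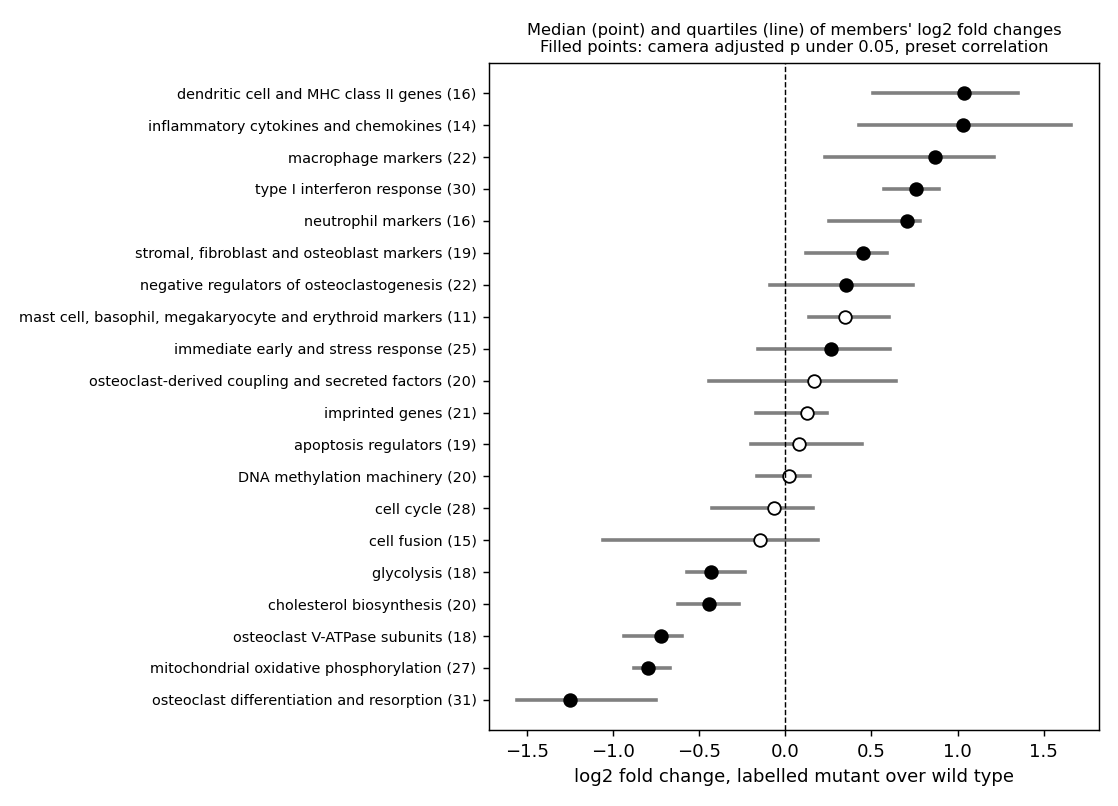
Median (point) and quartiles (line) of the log2 fold changes of the members of 20 gene lists, labelled mutant over wild type (horizontal axis), with the number of tested genes after each name; filled points passed camera at adjusted p under 0.05 with the preset correlation. The osteoclast list lay lowest, with a median of -1.25, and the MHC class II list highest, with a median of 1.04.

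Regulators and secreted products were mixed. Of 22 genes listed beforehand as negative regulators of osteoclast formation, 15 lay above 0 (median 0.35) and 0 passed over all genes. A place on the list does not show that a gene only restrains osteoclast formation, and the role of each was not tested. Adjusted over the list alone 4 rose and 3 fell. Those that rose included the transcription factor genes *Irf8*, *Cebpa* and *Bcl6*, and those that fell were *Nfkbia*, *Tnfaip3* and *Cyld*, which encode inhibitors of NF-kB signalling (named after their values were seen). *Irf8* stood at 178 ± 18.7 against 96.8 ± 35.0 CPM, *Nfkbia* at 145.5 ± 28.8 against 294 ± 65.1 CPM, and *Nfkb2* at 141 ± 39.4 against 210.5 ± 33.9 CPM. The list had a camera adjusted p of 0.0147, and adjusted p = 0.290 with an estimated correlation. Among 20 secreted and coupling factors 0 passed over all genes, and adjusted over the list alone 3 rose (*Apoe*, *C3* and *Cxcl16*) and 2 fell (*Sema4d* and *Cthrc1*). Of these *C3*, *Cxcl16* and *Cthrc1* were named after their values were seen, as were *Gadd45a* and *Ier3* below. The apolipoprotein gene *Apoe* stood at 10607 ± 1973 against 2345 ± 584 CPM, a log2 fold change of 2.18 (SE 0.261, edgeR adjusted p = 0.0544), and *Sema4d* at 388 ± 46.9 against 681 ± 147 CPM. Among 20 genes of the DNA methylation machinery 0 passed over all genes, and adjusted over the list alone 3 fell (*Tet2* and *Dnmt3a* among them) and 1 rose (*Gadd45a*). *Dnmt3a*, a de novo DNA methyltransferase gene, stood at 210.4 ± 36.3 against 442 ± 64.0 CPM, a log2 fold change of -1.07 (SE 0.176, edgeR adjusted p = 0.0764, and 0.0135 with the batch term), and *Idh1* at 361 ± 57.9 against 290.0 ± 89.1 CPM. The median (0.02) and mean (0.04) of this list lay above 0 while camera gave the direction down (adjusted p = 0.822). Secreted factors (camera adjusted p = 0.143) and 15 cell fusion genes (0.328, median -0.14) did not pass. *Sirpa* stood at 1518 ± 124 against 1519 ± 152.5 CPM and *Atp6v0d2* at 479 ± 238 against 1395 ± 449 CPM. Of 25 immediate early and stress genes 0 passed over all genes and 2 (*Ier3* and *Hmox1*) rose when adjusted over the list alone. *Hmox1* stood at 923 ± 177 against 421 ± 102 CPM and *Hspa5* at 920.4 ± 142 against 973 ± 195 CPM. The list had a camera adjusted p of 0.0256, adjusted p = 0.443 with an estimated correlation, and 0.172, 0.132 and 0.0562 without library 1, 3 or 5. Once the naming batch was a term, 5 negative regulators rose and 2 fell over all genes, as did 3 and 2 secreted factors, 2 and 3 methylation genes and 1 and 2 fusion genes, and both *Ier3* and *Hmox1* rose among the stress genes. The edgeR adjusted p with the batch term was 0.0135 for *Apoe*, 0.0272 for *Sema4d*, 0.0285 for *Nfkbia*, 0.0368 for *Irf8* and *Hmox1* and 0.0326 for *Atp6v0d2*, and 0.165 for *Nfkb2*.

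Markers of other cell types varied between libraries of the same genotype, in part along the naming batch. Of 16 neutrophil markers 13 lay above 0 (median 0.71) and 0 passed over all genes, and 1 (*Csf3r*, named after its value was seen) rose when adjusted over the list alone. *S100a9* stood at 233 ± 160.4 against 132 ± 105 CPM and *Ngp* at 215 ± 112 against 143 ± 91.5 CPM, both highest in libraries 5 and 6. Of 19 stromal and osteoblast markers 16 lay above 0 (median 0.45) and 0 passed over all genes or adjusted over the list alone. *Col1a1* stood at 1009 ± 676 against 676 ± 486 CPM and *Col1a2* at 855 ± 572 against 566 ± 371 CPM. With each library left out in turn, log2 fold changes ranged from 0.0883 to 1.73 for *S100a9* and 0.0697 to 1.28 for *Ngp*. The range was 0.0631 to 1.38 for *Col1a1*. The camera adjusted p was 0.0195 for neutrophil markers (adjusted p = 0.624 with an estimated correlation) and 0.0378 for stromal markers (adjusted p = 0.624 with an estimated correlation). Without library 1, 4 or 5 those values were 0.0679, 0.266 and 0.661 for neutrophil markers and 0.276, 0.105 and 0.685 for stromal markers. Among 11 mast cell, megakaryocyte and erythroid markers (camera adjusted p = 0.119) the platelet chemokine gene *Pf4* rose when adjusted over the list alone, at 98.8 ± 73.8 against 11.4 ± 7.08 CPM, and *Ppbp* stood at 20.9 ± 14.8 against 14.4 ± 7.33 CPM. Camera adjusted p-values were 0.370 for 28 cell cycle genes (*Pcna* 114 ± 18.2 against 96.6 ± 12.1 CPM, *Top2a* 69.8 ± 32.3 against 75.9 ± 9.89 CPM), 0.328 for 19 apoptosis regulators (*Mcl1* 677 ± 89.7 against 641 ± 63.1 CPM, *Birc3* 149.7 ± 8.56 against 197 ± 12.9 CPM) and 0.337 for 21 imprinted genes (*Gnas* 776 ± 303 against 752 ± 418 CPM, *Nnat* 388 ± 394 against 359.9 ± 418 CPM). Among the apoptosis regulators *Bid*, named after its value was seen, rose when adjusted over the list alone. In the fit with the naming batch, 6 neutrophil markers, the stromal marker *Postn*, *Pf4* and *Bid* rose over all genes, and the cell cycle gene *Ccne2* and the imprinted gene *Igf2r* fell (named after their values were seen). The edgeR adjusted p was then 0.0165 for *S100a9*, 0.0355 for *Ngp*, 0.0213 for *Csf3r* and 0.00526 for *Pf4*, and the neutrophil list passed fry with the batch term (adjusted p = 0.0445). Lymphocyte and germline lists had 4 tested genes each, too few for a set test. *Cd79b* stood at 10.3 ± 1.78 against 4.38 ± 1.85 CPM, *Ebf1* at 8.64 ± 5.84 against 5.11 ± 2.999 CPM, *Piwil2* at 3.07 ± 0.434 against 2.08 ± 0.636 CPM and *Dppa3* at 3.25 ± 1.63 against 2.94 ± 2.46 CPM.

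Over the 20 lists tested, camera with its preset correlation called 13, of which 8 were up and 5 down, and 0 of these calls held with an estimated correlation. That version takes its degrees of freedom from the 6 libraries, so few lists could pass whatever their correlation. The estimated correlation was 0.76 for the osteoclast list but -0.036 for negative regulators, below the preset 0.01. The camera adjusted p of the latter still went from 0.0147 to 0.290. The loss therefore does not show that a list was unchanged. Fry, whose p tests whether the genes of a list move on balance one way and does not compare the list with other genes, called 4: negative regulators (adjusted p = 0.00148), macrophage markers, inflammatory genes and cholesterol synthesis (adjusted p = 0.0498 for these 3). Its mixed p, which tests change in either direction, was after adjustment 1.31e-05 for stress genes, 0.00150 for inflammatory genes, 0.00309 for macrophage markers, 0.00373 for secreted factors, 0.00526 for the DNA methylation and negative regulator lists, 0.00760 for cholesterol synthesis and 0.0138 for apoptosis regulators, and above 0.05 for the other lists.

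Genes of pituitary hormones were abundant in 4 libraries, in both genotypes. *Gh*, which encodes growth hormone, had 17918 and 184265 counts in libraries 1 and 4 and 158499 and 51372 in libraries 2 and 3, but 0 in library 6 and 2 in library 5. *Pomc* had 4307, 27543, 29439 and 10061 counts in libraries 1, 4, 2 and 3, and 4 and 5 counts in libraries 6 and 5. The 7 hormone genes *Gh*, *Pomc*, *Cga*, *Tshb*, *Lhb*, *Fshb* and *Prl* took 0.256% of counts in library 1 (exact Clopper-Pearson 95% interval 0.253 to 0.260%), 1.74% in library 4 (1.74 to 1.75%), 1.34% in library 2 (1.33 to 1.34%) and 0.660% in library 3 (0.655 to 0.666%). In libraries 6 and 5 they had 4 and 7 counts in all. These intervals cover counting error only. The same 4 libraries held 1.36 to 2.46% of their counts in 8 pseudogenes, 7 of them on chromosome 1, and libraries 5 and 6 nearly none: *Gm10925* had 37956, 83294, 49065 and 39280 counts in libraries 1, 4, 2 and 3, and 1 and 0 in libraries 6 and 5. All 8 matched a mitochondrial transcript over 96.7 to 100% of aligned bases, so their counts are uncertain. *Nnat* followed the hormone genes, at 261, 819, 787 and 377 CPM in libraries 1, 4, 2 and 3 against 0 and 0.149 CPM in libraries 6 and 5.

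**Figure D4:**
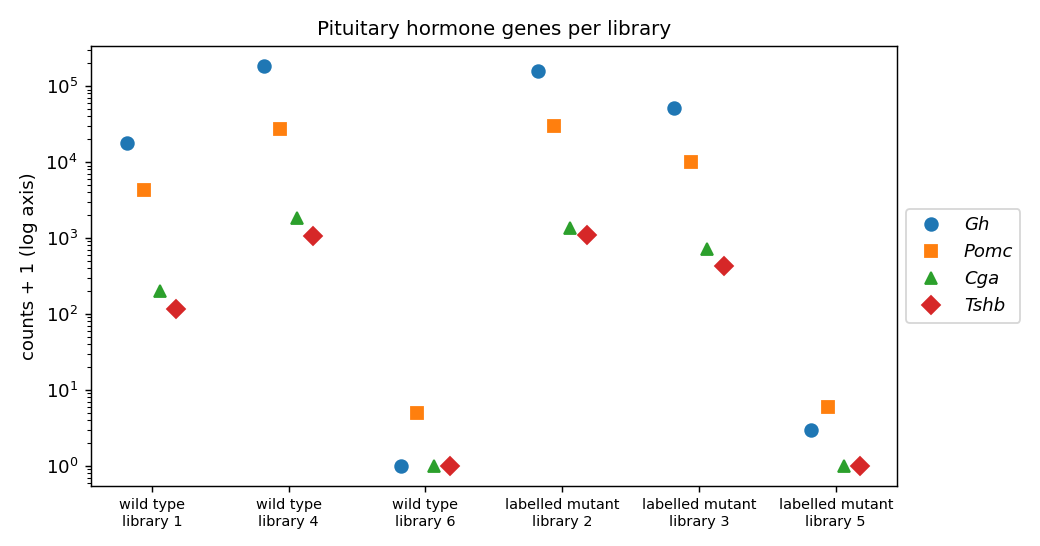
Counts plus 1 of the hormone genes *Gh*, *Pomc*, *Cga* and *Tshb* (vertical log axis) in each library (horizontal axis). *Gh* reached 184265 counts in library 4 and had 0 counts in library 6 and 2 in library 5.

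The labels give 1 female and 2 male samples per genotype but do not tie them to columns. *Xist*, the transcript of the inactive X chromosome, had 7328, 2762 and 1 counts in libraries 1, 4 and 6 and 9244, 748 and 1 in libraries 2, 3 and 5. *Ddx3y*, on the Y chromosome, had 27, 850 and 968 counts in libraries 1, 4 and 6 and 191, 736 and 1008 in libraries 2, 3 and 5, so *Xist* and *Ddx3y* were both present in libraries 1, 2, 3 and 4, at unlike levels. *Ddx3y* stood at 3.15 and 13.4 CPM in libraries 1 and 2 and at 65.8 to 77.6 CPM in the others. The Y-linked genes *Uty*, *Kdm5d* and *Eif2s3y* had 0, 19 and 21 counts in library 1 and 62, 76 and 185 in library 2. In the others they had 362 to 450, 378 to 476 and 647 to 1106 counts. Libraries 1 and 2, of different genotypes, thus had the most *Xist* and the least of the 4 Y-linked genes. Columns were not assigned to samples from their values, so no sex was assigned to a library and no test of sex was made.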

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

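The naming batch as a term, libraries 1 to 4 alone, leaving out libraries 2 and 4, and the filter on libraries 5 and 6 were chosen after seeing the data. The 7 genes higher and 3 lower in edgeR kept their direction under every alternative run, and the same counts came from DESeq2 size factors, from robust empirical Bayes and with a log2 fold change of 1 or more. Counts of genes higher and lower were 46 and 35 with no filter, 51 and 46 with a stricter filter, 120 and 196 with library quality weights in limma-voom, 233 and 312 at an adjusted p under 0.1, and 662 and 764 in DESeq2. They were 433 and 786 with the naming batch as a term, and 126 and 121 among 12133 genes at 1 CPM or more in libraries 5 and 6. All 10 genes were also called in DESeq2, with the batch term and with that filter. In libraries 1 to 4 alone edgeR called 1 and 0, with 1818 genes at an unadjusted p under 0.05 and 0 of the 10 genes called, and without libraries 2 and 4 it called 0 and 0, with 1915 such genes. Leaving out each library in turn gave 0 to 2 genes higher and 0 to 1 lower. Without library 2 there were 3 calls, 2 of them among the 10, and without library 6 there was 1, also among the 10. Without libraries 1, 3, 4 or 5 there were 0, with 2527, 2001, 2676 and 2345 genes at an unadjusted p under 0.05. Fewer libraries leave less power to pass; otherwise the cause was not tested. Scaling by DESeq2 size factors moved the median log2 fold change of all genes from -0.03 to 0.01. *Tet2* passed with library quality weights (-0.65), in DESeq2 (-0.54) and with the batch term (-0.57), its adjusted p ranging from 0.00635 to 0.285 over the alternatives. *Tet3* was above 0 throughout (0.11 to 0.30) and never passed.

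Camera called 13 of 20 lists, 0 with an estimated correlation, with or without the batch term, 4 in fry and 8 in fry with the batch term. With an estimated correlation the adjusted p was 0.443 for the osteoclast, V-ATPase, MHC class II, interferon, oxidative phosphorylation, cholesterol and stress lists, 0.290 for negative regulators, macrophage markers and inflammatory genes, 0.624 for neutrophil and stromal markers and 0.505 for glycolysis. With an estimated correlation and the batch term it was 0.276 for the osteoclast, V-ATPase, negative regulator, macrophage, neutrophil and oxidative phosphorylation lists, 0.297 for MHC class II, 0.516 for stromal and interferon, 0.217 for inflammatory, 0.280 for glycolysis and cholesterol and 0.557 for stress genes. In fry it was 0.190 for the osteoclast, V-ATPase and glycolysis lists, 0.227 for MHC class II and stress genes, 0.437 for neutrophil, 0.470 for stromal, 0.254 for interferon and 0.164 for oxidative phosphorylation genes. In fry with the batch term it was 0.0545 for osteoclast, 0.0552 for macrophage, 0.0959 for MHC class II and 0.283 for stromal, interferon and stress genes, and 0.049996 for mast cell and erythroid markers, which then passed. The mast cell and erythroid list also passed camera with no filter (0.0243), with the batch term (0.00302), in libraries 1 to 4 alone (0.00498) and without libraries 2 and 4 (0.0494), but not with an estimated correlation (0.443, and 0.276 with the batch term). Stress genes had 0.0523 with the batch term, and stromal markers 0.0591 with DESeq2 size factors and 0.0563 with the filter on libraries 5 and 6. In libraries 1 to 4 alone the secreted factors (0.0497) and cell cycle genes (0.000479) passed. Without libraries 2 and 4 imprinted genes passed (0.0445), and the direction turned for the DNA methylation (0.891) and cell cycle lists (0.135), neither of which passed. Apart from the few degrees of freedom of camera with an estimated correlation, the cause was not tested.

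Leaving out each library in turn, the camera adjusted p ranged from 1.39e-06 to 0.0562 for MHC class II, 4.21e-06 to 0.661 for neutrophil, 3.99e-05 to 0.685 for stromal, 0.00118 to 0.172 for stress, 0.0417 to 0.676 for cell fusion, 0.0144 to 0.490 for secreted factors, 0.0387 to 0.132 for mast cell and erythroid, 0.685 to 0.968 for DNA methylation, 0.00559 to 0.765 for cell cycle and 0.00172 to 0.676 for imprinted genes. Direction turned without library 1 or 2 for DNA methylation genes, without 2 for cell cycle genes and without 2 or 6 for imprinted genes. Of the 60 genes picked by the rule 12 turned in sign in at least 1 alternative, and none of these 12 passed the test. *Sirpa* was 0.0301 with the stricter filter, 0.0327 with DESeq2 size factors, 0.0329 in DESeq2 and 0.0272 with the filter on libraries 5 and 6. *Pkm* was 0.00241, 0.00330, 0.00328 and 0.000119 in the same 4. With quality weights *Mcl1* was -0.0892 and *Hspa5* 0.0187; in libraries 1 to 4 alone *Dppa3* was -0.0554. Without libraries 2 and 4 *Top2a* was 0.28, *Pkm* 0.0585, *Mcl1* -0.0401 and *Dppa3* -0.30. Leaving out each library in turn, log2 fold changes ranged from -0.0190 to 1.31 for *Col1a2*, -0.40 to 0.66 for *Ddx3y*, -0.33 to 0.95 for *Dppa3*, -0.26 to 0.63 for *Gnas*, -0.20 to 0.11 for *Hspa5*, -0.92 to 1.63 for *Nnat*, -0.19 to 0.11 for *Pkm*, -0.23 to 0.93 for *Ppbp*, -0.0538 to 0.0818 for *Sirpa*, -0.46 to 0.23 for *Top2a* and -3.21 to 1.17 for *Xist*. No paired analysis was possible because the columns carry no replicate numbers, by which pairs would be made, and samples were not assigned from values. Sex as a covariate, male libraries alone and a genotype-by-sex interaction were not run, since the columns are not tied to a sex. Other pseudocounts were not run, as the count test uses none, and median-of-ratios scaling is that of DESeq2 size factors.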

Other observations

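In the fit with the naming batch as a term, chosen after seeing the data, the rule for naming genes gave further genes with large changes, of which those with a mean of at least 10 CPM in either group, a cut-off set while writing, are given here. *Fcrls*, an Fc receptor-like gene, rose from 22.3 CPM ± 9.16 to 236 CPM ± 49.9 (SD, n = 3 each), a log2 fold change of 3.47 (SE 0.167, edgeR adjusted p = 0.00195). *F13a1*, which encodes the A chain of coagulation factor XIII, rose from 99.9 ± 41.1 to 557 ± 89.1 CPM, *Wfdc17* from 23.4 ± 5.69 to 97.6 ± 22.3 CPM, *Nxpe5* from 16.5 ± 5.87 to 69.6 ± 3.55 CPM and the receptor gene *Gpr34* from 6.43 ± 3.02 to 22.9 ± 0.393 CPM. The cytokine receptor gene *Il21r* rose from 17.8 ± 6.14 to 66.0 ± 17.5 CPM and *Angptl4* from 6.91 ± 0.197 to 34.7 ± 15.8 CPM. The actin-associated gene *Synpo2* fell from 41.5 ± 2.96 to 6.87 ± 3.13 CPM, *Serpind1*, which encodes heparin cofactor II, from 31.9 ± 16.4 to 5.74 ± 3.43 CPM, the neuropeptide gene *Nmb* from 18.4 ± 5.29 to 2.96 ± 1.15 CPM and the endocytic receptor gene *Cubn* from 15.0 ± 3.69 to 1.92 ± 1.54 CPM. With genotype as the only term none of these 11 passed, with edgeR adjusted p-values from 0.0544 to 0.106.

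Of the tests below, those on how reads were assigned and on osteoclast and macrophage genes were chosen after the results were seen. Pituitary hormone genes were abundant in libraries 1 to 4 and nearly absent from libraries 5 and 6. Of 9 further pituitary genes picked before their counts were examined, 6 were higher in each of libraries 1 to 4 than in both others, which is consistent with RNA from pituitary gland in those libraries. Markers of islet, adrenal, glia and placenta reached 0.809% of the summed CPM of *Gh*, *Cga*, *Tshb*, *Lhb* and *Fshb* in library 4, mostly from *Mbp*, which was at 88.6 to 136 CPM in every library, and this argues against those tissues. Library 1 to library 4 ratios were 4.82 times higher for the mitochondrial-like pseudogenes (0.706, median) than for the same 5 hormone genes (0.146, median). Both come from different RNAs whose amounts can differ under any read assignment, so this does not decide whether reads were assigned in another way, which stays open. *Prl*, an abundant transcript of the adult gland, had only 95 counts in library 4 against 184265 for *Gh*. This is 1 gene, with no reference ratio by age or sex to set it against. The age or part of a gland therefore stays open. No biological explanation was tested, as the pattern does not follow genotype, and the labels name bone marrow cultures only.

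Most osteoclast genes had lower and most macrophage genes higher means in the libraries labelled mutant, though 0 of 31 and 1 of 22 passed over all genes and both lists were lost with an estimated correlation (adjusted p = 0.443 and 0.290). Pituitary RNA as the cause is argued against by libraries 5 and 6, which lack it and where the median log2 ratio of the osteoclast list was -1.32, with 30 of 31 genes lower in library 5. A larger share of stromal cells as the only cause would lower both groups, but the lower quartile of the macrophage list was 0.23. That list was already known to lie above 0, and macrophage genes can rise while stromal RNA rises too. Of 19 stromal markers 16 lay above 0 (median 0.45), so a stromal part in the pattern stays open. Sequencing depth would need shallower libraries labelled mutant, and 2 of the 9 pairs of a library labelled mutant and a wild-type library were such. CPM values are already scaled for library totals, and the totals were known beforehand, so no conclusion is drawn from this count. The labelled genotype and how the cultures ran both stay open, untested, as no value here separates them.

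More genes passed with the naming batch as a term, 1219 against 10. If the naming batch is a real source of spread, its pair of libraries should give more calls than other pairs of a wild-type library and one labelled mutant set apart in the same way; 1 of the 9 pairs, libraries 5 and 6 themselves, gave as many as 1219, and the next, libraries 2 and 4, gave 300. Libraries 5 and 6 also lay together at the same end of the leading principal component and nearly lacked the hormone genes. Libraries 2 and 4 lay furthest towards its other end, with hormone shares of 1.34 and 1.74%. The ranking of pairs follows that split, so it is not separate support for a naming batch. Counts of the 8 mitochondrial-like pseudogenes also split along the names. They took 1.36 to 2.46% of counts in libraries 1 to 4, in both genotypes, against 6.2e-05% in library 6 and 4.3e-05% in library 5. These values argue against libraries 5 and 6 having been handled like libraries 1 to 4 at every step. Neither the names nor the values say which step differed. Whether the same difference gave the spread in other genes stays open. Of the 10 splits of the 6 libraries, 1, the real one, gave as many genes, with 10 calls against 0 as the highest other, and with the batch term it was again 1, with 1219 against 0. With 10 splits no share under 0.05 can be had. The other splits mix the genotypes, so a difference between genotypes adds to their spread and lowers their calls. With the batch term, some, such as libraries 1, 2 and 4 against the others, put libraries 5 and 6 on the same side. Their groups are then partly confounded with the naming batch, so no conclusion is drawn from the contrast with 0.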
